A study of Mus musculus with 8 samples.

How the data were processed

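Bulk RNA was measured in CD8 T cells from Py8119 tumours, in 8 libraries: 4 from Mtdh KO hosts and 4 from WT hosts. Per the labels' protocols, tumours were dissociated, red cells were lysed, and live CD45+CD3e+CD8+ cells were sorted. Per the same protocols, total RNA was extracted with a micro-scale column kit, ribosomal RNA was depleted with QIAseq FastSelect, and libraries were made with PrepX chemistry on an Apollo 324 instrument. Strand was not stated, so overlapping and antisense genes such as Xist and Tsix cannot be told apart. The submitters' processing notes name Partek, STAR 2.7.8a, DESeq2 and the mm39 build, without saying what each was used for.

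The deposited values are a signal per gene and library: read counts that the authors estimated per gene and divided by a DESeq2 size factor, as the name of the table says. The values themselves were examined. In each library the low values were mostly multiples of a step of 0.788 to 1.30, taken as the worth of 1 read. Within 0.02 reads, 81.4% to 87.9% of values of up to 500 reads were whole, and the rest were fractions, as when reads are shared between similar genes. Whole reads were therefore not recovered and no count model was run. Dividing each column's sum by its step gave an estimated depth of 16400000 to 29600000 reads. Listed genes numbered 19673, and 19544 of their identifiers are in the reference annotation supplied for the mouse genome. Genes with repeated or missing names, 131 in all, were kept by identifier. Symbols and positions are those of the authors' table on mm39, with the end taken as 1 less than the listed stop, since the difference of stop and start equals the gene length for 98.5% of matched genes. Small nuclear and nucleolar RNAs, 321 genes, held 28.6% to 36.3% of each library's sum.

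The number of distinct cDNA fragments behind each library was estimated from genes other than small RNAs with a mean of 20 to 500 in the other libraries. Of these, 9.1% to 45.0% were undetected, with under 3 reads, and the fragment number was the one at which a Poisson draw leaves out that share. The estimate was 120000 to 585000 fragments, or 27.9 to 129 reads per fragment. KO and WT libraries differed in log2 fragments by -0.54 (exact two-sided permutation p = 0.343). Precision is thus set by fragments and by the spread between 4 animals, not by reads.

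Values were used as log2(value + 1) without further scaling. Genes with a mean of at least 10 over the 8 libraries, 16120 in all, were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), KO against WT, without covariates. The test was two-sided, p-values were adjusted by Benjamini-Hochberg, and the threshold was 0.05. Fold changes are KO over WT, and means are arithmetic means of normalized values with the SD over 4 libraries. Mtdh was also tested by an exact permutation of the group labels.

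Lists of genes for T cell function, lipid and energy metabolism, stress, and markers of the cell types that a tumour sort could hold were fixed before the data were examined, as were the main model, the alternatives other than those named below as added, and the rule for naming genes. Lists with at least 5 tested genes, 29 in all, were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. Fry asks whether the genes of a list move one way on balance and does not compare them with other genes. For each list the count of genes past 0.05 was also adjusted over the list alone. Members shared with another list ranged up to 6, in the chemokine list.

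The naming rule took Mtdh, then up to 10 genes per direction. These were genes past the threshold with a mean of at least 50 and no overlap between groups, ordered by size of change, and, where fewer than 10 met this, the genes with the smallest p in that direction, said not to pass. It also took from each list the 2 genes with the smallest p and the 1 with the highest mean, which gave 104 genes, some of which are not reported here. Predicted genes and pseudogenes were counted but not named among the leading genes.

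The model and list tests were tested on simulated values with the real genes' means and spread, in which genes with a mean of at least 1000 were changed by known amounts. For KO against WT, with 16120 genes, 46% of 100 genes changed by 1 on the log2 scale were recovered, 98% of 50 genes changed by 2 and 100% of 50 genes changed by 3, with 11 false calls among 156. With no change simulated, 0 genes and 0 of 29 lists were called. Noise was drawn independently for each gene, so this does not show how often lists of correlated genes are called by chance. Loss of fragments was not simulated.

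Alternatives covered the pseudocount, the minimum mean, TMM, quantile and upper-quartile scaling, a replicate block, sample weights, robust hyperparameters, each library left out in turn, and the estimated correlation. Added after the data had been seen were a pseudocount of 100, a batch term for libraries 1 and 2 against 3 and 4, each of those 2 sets alone, both libraries numbered 2 left out, and the mean of the CD8 T cell or macrophage markers as a covariate. The added settings were applied to the counts, Mtdh and the lists, a restriction made after it was seen how often uncalled genes changed sign under them. The genes past the threshold in the cytotoxic, inhibitory receptor and TCR lists and 4 MHC class II genes were followed under the CD8 covariate alone. TMM was computed from its definition, without the weights of the original method. Files were read and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Genes on the Y chromosome in the sex-linked list were not analysed here.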

Results

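RNA was sequenced from live CD45+CD3e+CD8+ cells sorted out of tumours grown from Py8119, a mouse mammary tumour cell line. The tumours grew in hosts that lacked Mtdh (metadherin), the KO group, or in wild-type hosts, the WT group, and each group had 4 biological replicates, written here as KO or WT library 1 to 4. The comparison asks how loss of Mtdh in the host alters gene expression in the tumour's CD8 T cells, and the series title sets this beside lipid metabolism of the host liver. The values were gene-level estimated counts that the authors had normalized with DESeq2, and 16120 of 19673 listed genes had a mean of at least 10 and were tested. The estimated depth was 16400000 to 29600000 reads per library, spread over an estimated 120000 to 585000 amplified cDNA fragments. A single fragment corresponded to a normalized value of 25.5 in the most complex library and 142 in the least complex one, so values near these rest on few fragments. Intervals and floors that cover counting error of single libraries are not given, since reads copied from the same fragment are not independent.

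Mtdh (ENSMUSG00000022255, chromosome 15, 34082840 to 34145770 of mm39) was lower in all 4 KO libraries than in any WT library. Its normalized value was 3905 ± 1179 (SD, n = 4) in KO and 9113 ± 2699 (SD, n = 4) in WT. The KO values were 5118, 4622, 2538 and 3341, and the WT values were 9324, 12745, 6407 and 7974. The log2 fold change was -1.23 (SE 0.25, limma adjusted p = 0.0400), so the KO libraries kept 42.6% of the WT level. An exact two-sided permutation test of the mean log2 values gave p = 0.0286, the smallest that the 70 arrangements allow. The gene-level value does not resolve which exons were deleted, or which cells the remaining transcripts came from. The limma call ended without KO library 2 (adjusted p = 0.0560), KO library 3 (0.0673), KO library 4 (0.193), WT library 1 (0.241) or WT library 2 (0.168), and it ended with a minimum mean of 50 (0.0945).

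Of the 34 genes that were higher in KO, 10 are described here by size of change. Il2ra, the alpha chain of the IL-2 receptor (ENSMUSG00000026770, chromosome 2, 11647618 to 11698004), rose 11.9-fold, from 86.6 ± 42.8 in WT to 913 ± 247 in KO (SD, n = 4 each; log2 fold change 3.57, SE 0.62, limma adjusted p = 0.0127). The WT values of Il2ra were 123, 101, 24.6 and 97.8 in WT libraries 1 to 4, where a single fragment was worth 62.2, 64.7, 25.5 and 33.4. The size of its fold change thus rests on few WT fragments. Prf1, which encodes the pore-forming protein perforin (ENSMUSG00000037202, chromosome 10, 61133612 to 61140459), rose 8.63-fold, from 197 ± 123 to 1468 ± 326 (SE 0.47, limma adjusted p = 0.00466). Prf1 was at 80.0 and 107 in WT libraries 1 and 2, and at 262 and 337 in WT libraries 3 and 4. In WT libraries 1 and 2 its value rests on few fragments. Cxcl9, an interferon-induced chemokine that attracts T cells (ENSMUSG00000029417, chromosome 5, 92469206 to 92475938), rose 8.39-fold, from 263 ± 88.6 to 2271 ± 899 (SE 0.40, limma adjusted p = 0.00139). The interferon-induced GTPases Iigp1 and Gbp2 rose by log2 fold changes of 2.86 (SE 0.39) and 2.24 (SE 0.30), and both belong to families of similar genes whose reads can be hard to part. Serpinb9, an inhibitor of granzyme B, rose by 2.37 (SE 0.29), the inhibitory receptor Ctla4 by 2.51 (SE 0.42) and the costimulatory receptor Tnfrsf9 (4-1BB) by 2.26 (SE 0.43). Dusp4, a phosphatase that dampens MAP kinase signalling, rose by 2.53 (SE 0.42), and Dcstamp, a fusion protein of osteoclasts and other myeloid cells, by 2.42 (SE 0.40). Single WT values also rest on few fragments for Cxcl9 (140), Dusp4 (98.6) and Dcstamp (143) in WT library 1, and for Ctla4 (124) in WT library 2. Without KO library 4 the calls of Il2ra (adjusted p = 0.0922), Prf1 (0.0575), Dusp4 (0.0721), Ctla4 (0.0578), Dcstamp (0.0721) and Tnfrsf9 (0.191) ended, without KO library 1 those of Il2ra (0.0736) and Tnfrsf9 (0.109), and without WT library 1 those of Ctla4 (0.0509) and Tnfrsf9 (0.151). The Tnfrsf9 call also ended without WT library 2 (0.0824) or WT library 3 (0.0551), whereas those of Cxcl9, Iigp1, Serpinb9 and Gbp2 held in each of the 8 omissions.

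**Figure D1:**
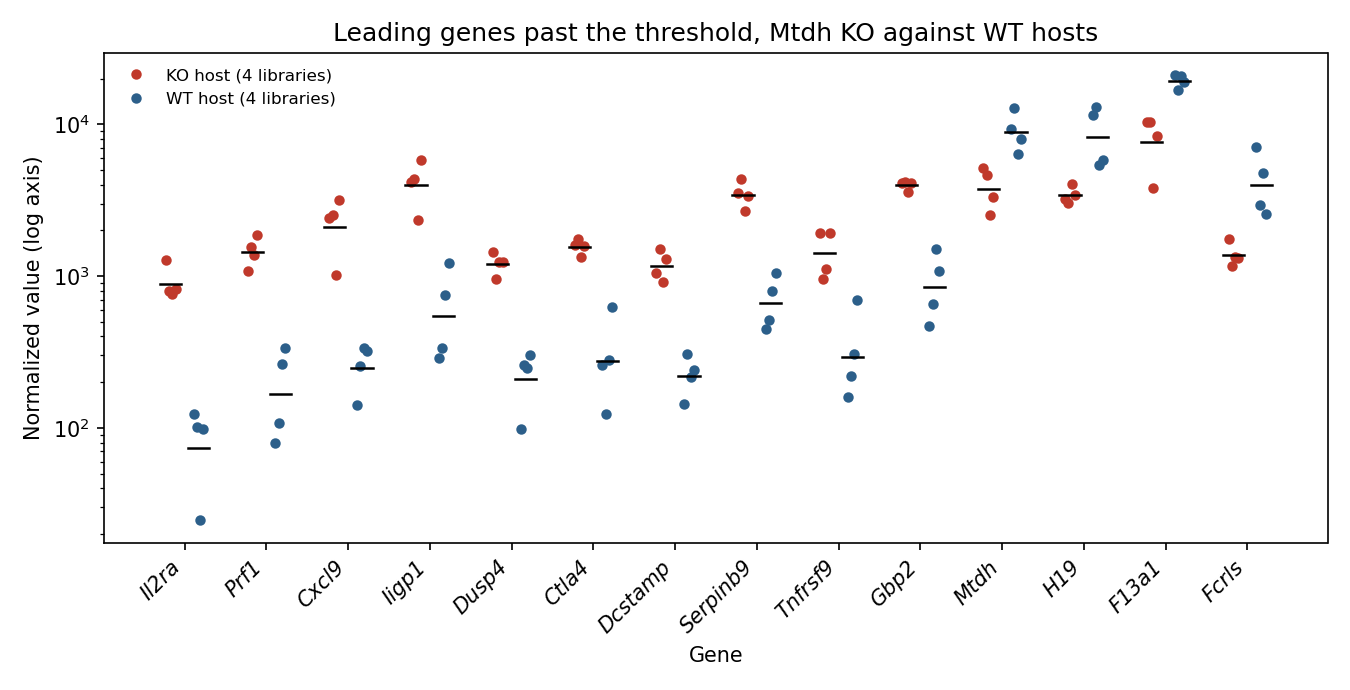
Normalized values of the leading genes past the threshold on a log axis, one point per library (KO host red, WT host blue, 4 each), with a bar at the mean of the log2 values. Il2ra lies between 762 and 1282 in KO and between 24.6 and 123 in WT, and Mtdh, H19, F13a1 and Fcrls are lower in every KO library than in any WT library.

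Gene lists fixed beforehand for T cell function were higher in KO by camera at a preset correlation of 0.01, although none of these calls held when the correlation was estimated from the data. In the cytotoxic effector list, 2 of 18 tested genes (Prf1 and Nkg7, a cytotoxic granule protein, log2 fold change 1.54) passed over all genes and 4 when adjusted over the list alone, and the list median was 1.13 (camera adjusted p = 1.89e-06; adjusted p = 0.187 with an estimated correlation). Among inhibitory receptor and exhaustion genes, 2 of 22 passed, Ctla4 and Ikzf2 (the transcription factor Helios, 1.15), and 11 passed when adjusted over the list alone. Its median was 0.65 (camera adjusted p = 7.97e-08; adjusted p = 0.187 with an estimated correlation). Among TCR signalling and immediate early genes, 5 of 24 passed: Il2ra, Tnfrsf9, Fosl2 (an AP-1 subunit, 1.32), Dusp5 and Nr4a3. When adjusted over the list alone 9 were higher and 1 was lower (Fos, named here after its values were seen), with a median of 0.37 (camera adjusted p = 1.38e-05; adjusted p = 0.148 with an estimated correlation), and this was the only list that fry called (adjusted p = 0.0327). Fosb, the most abundant gene of that list, had a log2 fold change of 0.32 (SE 0.23; 0.18 without KO library 2 and 0.49 without KO library 3), which did not pass. In the naive, memory and stem-like list, 1 of 22 genes passed, Il2rb (the IL-2 and IL-15 receptor beta chain, 1.83), and 3 when adjusted over the list alone, with a median of 0.31 (camera adjusted p = 0.0147; adjusted p = 0.545 with an estimated correlation). The tissue residency list had no gene past the threshold over all genes and 3 when adjusted over the list alone, with Bhlhe40 at 1.02 (SE 0.24) and Cxcr6 at 1.06 (SE 0.26), and a median of 0.30 (camera adjusted p = 0.00843; adjusted p = 0.187 with an estimated correlation). Chemokines and their receptors had a median of 0.29 (camera adjusted p = 0.0357; adjusted p = 0.357 with an estimated correlation), with 0 of 19 genes past the threshold and 1 when adjusted over the list alone. Of the genes named here as past the threshold, Ikzf2 passed in 2 of the 8 omissions of a library (adjusted p up to 0.264), Fosl2 in 3 (up to 0.202), Dusp5 in 3 (up to 0.123) and Nr4a3 in 3 (up to 0.258). The calls of Nkg7 (0.0575 and 0.0509) and Il2rb (0.0575 and 0.0523) ended without KO library 4 or WT library 1. The TCR median was 0.21 without KO library 2, the residency median 0.51 without WT library 4, and the chemokine median 0.54 without KO library 2, 0.48 without WT library 1 and 0.17 without WT library 2.

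The 12 markers of CD8 T cells had a median of 0.74, 11 of them positive (camera adjusted p = 0.00314; adjusted p = 0.518 with an estimated correlation). Cd3e had a log2 fold change of 1.31 (SE 0.31) and Cd8a of 1.15 (SE 0.34), neither past the threshold, and both passed when adjusted over the list alone. Without WT library 2 Cd8a was at 0.66. Cd8a was lowest in WT library 2, at 1565 against 5712 to 6545 in the other WT libraries. An exact two-sided permutation test of the mean log2 of the 12 markers gave p = 0.486, with a KO minus WT difference of 0.75. The CD8 call ended without KO library 3 (camera adjusted p = 0.0752) or WT library 2 (0.238), and so did the naive and memory call (0.283 and 0.241). The CD8 median was 1.28 without KO library 1, 0.25 without WT library 2 and 1.11 without WT library 4. The naive and memory median was 0.68 without KO library 1, 0.02 without KO library 3 and 0.12 without WT library 2. The residency call ended without WT library 2 (0.0528), and the chemokine call without KO library 1 (0.102), KO library 4 (0.127), WT library 2 (0.149), WT library 3 (0.0522) or WT library 4 (0.0528).

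In KO, 3 genes of antigen presentation by MHC class II passed the threshold and a further one, H2-Ab1, did not (log2 fold change 1.59, limma adjusted p = 0.0828), its values overlapping between the groups. H2-Aa (ENSMUSG00000036594, chromosome 17, 34501718 to 34506797) rose 3.49-fold, from 17512 ± 5300 to 63536 ± 23713 (SD, n = 4 each; log2 fold change 1.80, SE 0.29, limma adjusted p = 0.00762). H2-Eb1 rose by 1.73 (SE 0.28) and Cd74, the invariant chain that chaperones class II molecules, by 1.54 (SE 0.23). These genes stood in the dendritic cell list, of which 3 of 13 passed over all genes and 4 when adjusted over the list alone, with a median of 1.47 (camera adjusted p = 1.38e-05; adjusted p = 0.187 with an estimated correlation), or 0.83 without KO library 1. Calls of H2-Aa and H2-Eb1 ended without KO library 4 (adjusted p = 0.0577 for both), and that of H2-Aa also without WT library 1 (0.0602) and with robust hyperparameters (0.157). The type I interferon list had a median of 0.51 with 25 of 33 genes positive (camera adjusted p = 9.93e-05; adjusted p = 0.390 with an estimated correlation). None of its genes passed over all genes.

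Only 4 genes were lower in KO and past the threshold: Mtdh, Fcrls, F13a1 and H19. Fcrls, an Fc receptor-like gene of macrophages and microglia (ENSMUSG00000015852, chromosome 3, 87158065 to 87171045), was 2.90-fold lower, at 1392 ± 247 in KO and 4344 ± 2082 in WT (SD, n = 4 each; log2 fold change -1.54, SE 0.29, limma adjusted p = 0.0224). F13a1, which encodes a coagulation factor subunit made by macrophages (ENSMUSG00000039109, chromosome 13, 37051152 to 37234220), was 2.54-fold lower, at 8196 ± 3081 and 19425 ± 1919 (log2 fold change -1.34, SE 0.26, limma adjusted p = 0.0291). The imprinted noncoding RNA H19 had a log2 fold change of -1.28 (SE 0.26, limma adjusted p = 0.0426). Each of these 3 calls ended without KO library 4 or WT library 1, with limma adjusted p of up to 0.175 for Fcrls, 0.211 for F13a1 and 0.324 for H19. They ended also without KO library 2 or WT library 3 for Fcrls, WT library 2 or 3 for F13a1, and KO library 1 or 2 or WT library 2 for H19. The next genes by unadjusted p in this direction did not pass: Pcdhgc3 (-1.39, SE 0.34), which shares exons with its gene cluster, Selenop (-0.97, SE 0.24), Stab1 (-0.98, SE 0.24), Gas1 (-1.11, SE 0.28), Col6a2 (-1.62, SE 0.41) and Abca9 (-1.40, SE 0.35). Macrophage and monocyte markers moved in the same direction as Fcrls and F13a1, with a median of -0.46 and 17 of 19 negative (camera adjusted p = 0.0230; adjusted p = 0.545 with an estimated correlation). None of the 19 passed over all genes, and 2 were lower when adjusted over the list alone, Mrc1 at -0.73 (SE 0.21) and Spp1 at -0.73 (SE 0.20). That call ended without KO library 2 (0.0961), KO library 3 (0.293) or WT library 1 (0.291), and with sample weights (0.0925, median -0.25).

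None of the 6 lipid lists changed by camera, and none of their genes passed over all genes tested or when adjusted over a list alone. Fatty acid oxidation had a median log2 fold change of -0.42 with 21 of 30 genes negative (camera adjusted p = 0.368), including Acox3 at -0.75 (SE 0.36; -0.43 without KO library 1). Lipid uptake and storage had a median of -0.09 (camera adjusted p = 0.988), with Vldlr at -1.21 (SE 0.42) and Dgat1 at 1.16 (SE 0.48). Fatty acid synthesis had a median of -0.0055 (camera adjusted p = 0.934) and cholesterol synthesis of 0.08 (camera adjusted p = 0.372). Cholesterol efflux and LXR targets had a median of -0.26 (camera adjusted p = 0.317), and lipid peroxidation, iron and glutathione genes of -0.09 (camera adjusted p = 0.988). Among the other lists, glycolysis had a median of 0.12 (camera adjusted p = 0.0747), with the glucose transporter Slc2a1 at 1.08 (SE 0.33). Oxidative phosphorylation (-0.03, camera adjusted p = 0.968), the unfolded protein response (0.0097, 0.714), heat shock (-0.16, 0.372) and proliferation (0.0091, 0.968) did not pass. Apoptosis and p53 targets did not pass either (-0.23, 0.314), though Cdkn1a, a cell cycle inhibitor, was at 1.28 (SE 0.28, limma adjusted p = 0.0594) and passed when adjusted over the list alone. The median, the mean and the test's direction differed in sign for proliferation, fatty acid synthesis, cholesterol synthesis, lipid peroxidation, oxidative phosphorylation, the unfolded protein response and apoptosis.

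Transcripts of cells outside the CD8 gate were present in every library. The macrophage gene Lyz2 ranged from 75242 to 211543 and the T cell gene Cd8a from 1565 to 13355. Fibroblast markers had a median of -0.55 (camera adjusted p = 0.0490; adjusted p = 0.518 with an estimated correlation), with 0 of 14 genes past the threshold over all genes and 1, Postn at -1.33 (SE 0.35), when adjusted over the list alone. Red blood cell and platelet markers had a median of -2.93 (camera adjusted p = 6.96e-04; adjusted p = 0.187 with an estimated correlation), at low levels and after red cell lysis. None of its 5 tested genes passed over all genes and 1 passed when adjusted over the list alone, Hbb-bs, whose copies share reads and which lay at 0 to 1.10 in KO and 68.8 to 177 in WT. CD4 and regulatory T cell markers had a median of 0.90 (camera adjusted p = 0.0159; adjusted p = 0.194 with an estimated correlation), and 1 of its 6 tested genes, Il2ra, passed. B and plasma cell markers had a median of 0.15 (camera adjusted p = 0.0291; adjusted p = 0.518 with an estimated correlation), with Igkc at 2.55 (SE 0.69), the 1 gene past when adjusted over the list alone. NK and gamma-delta T cell markers (median 0.33, camera adjusted p = 0.372), tumour and epithelial markers (0.35, 0.368) and endothelial markers (-0.65, 0.934) did not pass. Fewer than 5 neutrophil and mast cell, adipocyte and sex-linked genes were tested, so these lists have no test, and Xist lay between 25699 and 60463 in every library. The CD4 call ended without KO library 1 (0.0676), KO library 3 (0.0949, median 0.12), KO library 4 (0.110), WT library 2 (0.101, median -0.08) or WT library 4 (0.115, median -0.04). The B cell call ended without KO library 1 (0.0781), KO library 3 (0.182, median -0.16), KO library 4 (0.110), WT library 2 (0.110, median -0.31), WT library 3 (0.0636) or WT library 4 (0.0602), and its median was 0.86 without KO library 2 and 0.24 to 0.38 in the other 5 omissions. The fibroblast call ended without KO library 2 (0.102), KO library 3 (0.113), KO library 4 (0.443), WT library 1 (0.0533), WT library 2 (0.356, median -0.35) or WT library 3 (0.0642), and its median was -1.05 without KO library 1. Without WT library 1, 3 or 4 fewer than 5 red blood cell and platelet genes were tested, so that list has no test there.

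**Figure D2:**
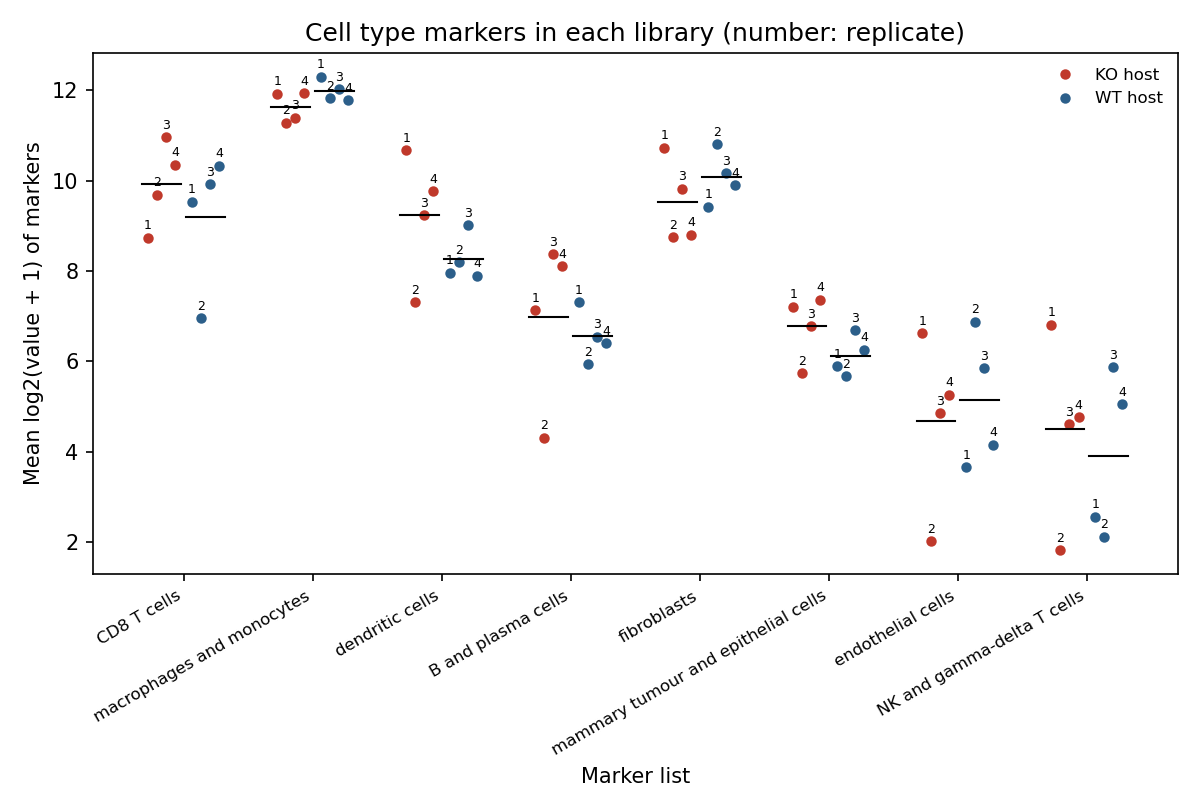
Mean log2(value + 1) of the tested markers of 8 cell types, one point per library with its replicate number (KO host red, WT host blue), with a bar at the group mean. CD8 T cell markers range from 6.95 in WT library 2 to 10.96 in KO library 3, and macrophage and monocyte markers lie between 11.28 and 12.30 in all 8 libraries.

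**Figure D3:**
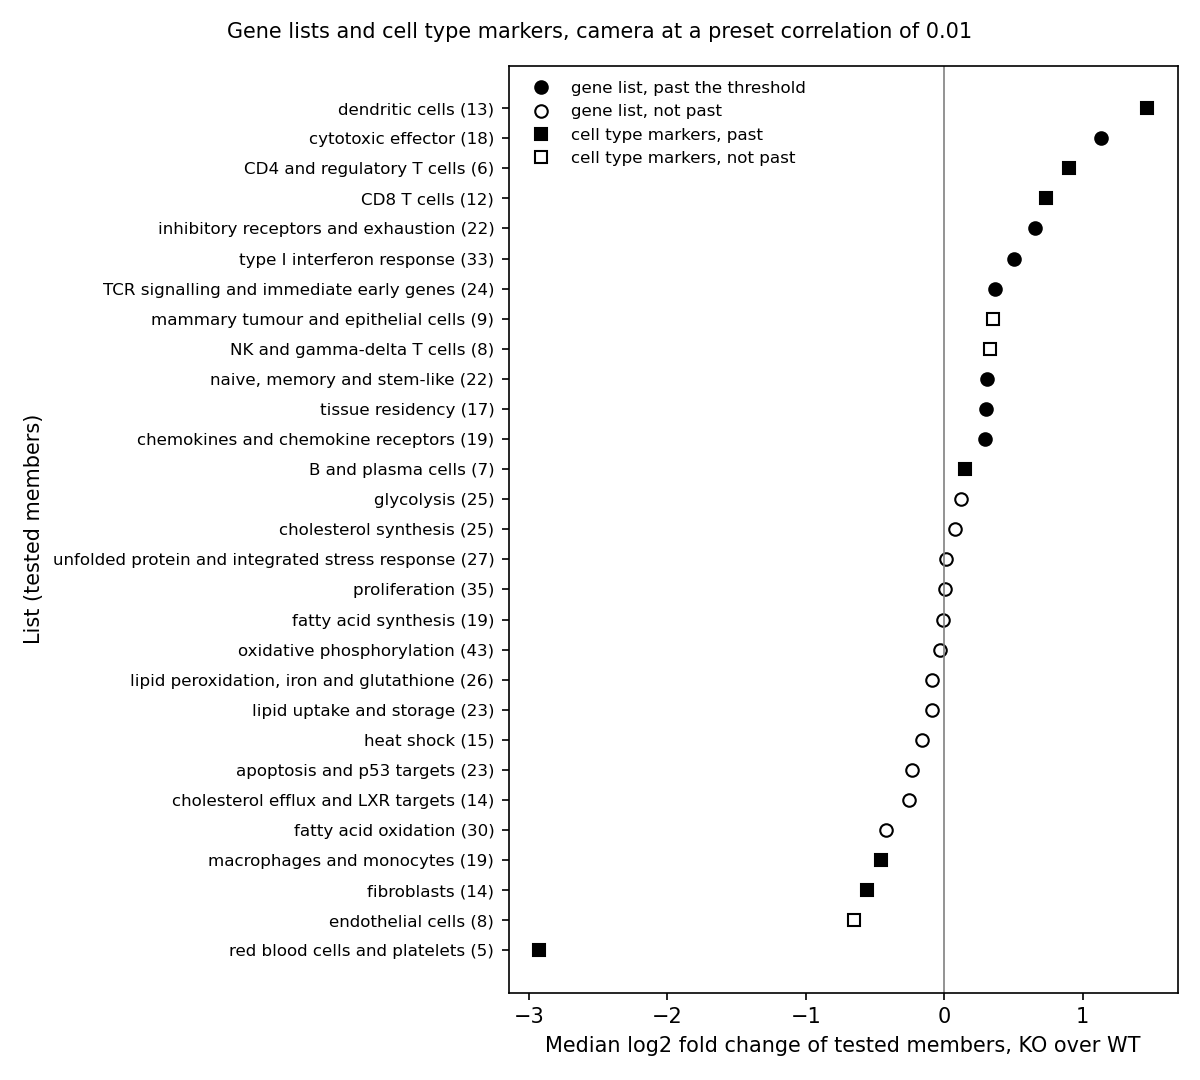
Median log2 fold change, KO over WT, of the tested members of each gene list (circles) and cell type marker list (squares), with the number of tested members in brackets. Filled symbols mark the 14 lists past a camera adjusted p of 0.05 at a preset correlation of 0.01, 11 of them higher and 3 lower, and 0 of them pass with an estimated correlation.

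In all, 38 genes passed limma's adjusted p threshold of 0.05, 34 higher and 4 lower in KO, with absolute log2 fold changes between 1.15 and 3.57. At an unadjusted p under 0.05 there were 1080 genes, 518 higher and 562 lower. All 38 had KO and WT values that did not overlap, as did 662 of all tested genes, or 4.11% against the 2.86% that chance gives. The count of genes past the threshold depended on single libraries: it was 7 without KO library 4, 11 without WT library 1, 22 without WT library 3, 23 without KO library 1, 24 without KO library 2 or WT library 2, and 70 without WT library 4. With a minimum mean of 50 it was 15, all higher in KO, and the calls of Mtdh, Fcrls (0.0608), F13a1 (0.0945), H19 (0.103), H2-Aa (0.0525), Tnfrsf9 (0.0775), Ikzf2 (0.0608), Fosl2 (0.0608), Dusp5 (0.0525) and Nr4a3 (0.109) ended. In other planned settings those of H19 with a pseudocount of 0.5 (0.0541), Ikzf2 with upper-quartile scaling (0.0507) and Nr4a3 with robust hyperparameters (0.241) ended. Libraries 1 and 2 of both groups also differed from libraries 3 and 4 in 29 genes, and within these 2 sets of 4 libraries the Mtdh log2 fold change was -1.16 and -1.30. That of Il2ra was 3.17 and 3.97, and that of Prf1 3.79 and 2.43. In either set alone 0 genes passed limma. An unadjusted p under 0.05 was found for 746 of 15383 and 815 of 16105 tested genes, near the share of 0.05 that chance alone gives.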

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

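All tests in this part were chosen after the results they address had been seen, except the rule for single libraries, which was fixed beforehand. That rule, Dixon's test at 95%, marks a library whose gap to the nearest of its group takes up most of the group's range. Chance marks about 1 group in 20, and here 13 of 207 groups were marked, or 6.28%. Values under 0.5 were set to 0, a step added after a value of 1.02e-24 for Tsix had been marked. KO library 3 and WT library 2 held 5 of the 13 each.

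Il2ra was 1282 in KO library 1 and 762 to 816 in the other KO libraries. Gbp2 was 3587 in KO library 3 and 4101 to 4165 in the others. Srebf1, a regulator of fatty acid synthesis, was 431 in KO library 3 and 603 to 626 in the others. Hmgcs1, an enzyme of cholesterol synthesis, was 4353 in WT library 2 and 3514 to 3595 in the others. The cholesterol transporter gene Abca1 was 10062 in KO library 3 and 18754 to 20364 in the others. The chaperone gene Hspa8 was 12816 in WT library 4 and 9667 to 10186 in the others. Cd8a was 1565 in WT library 2 and 5712 to 6545 in the others. The macrophage gene Mrc1 was 19912 in WT library 1 and 15259 to 16006 in the others. The endothelial gene Cdh5 was 1237 in WT library 2 and 101 to 227 in the others. Hba-a2 was 1.30 in KO library 3 and 0 in the others, which is below the value of 1 fragment. Plin4 was 77.9 in KO library 3 and 0 in the others. In WT libraries Plin4 was 103 in library 2 and 0 to 7.29 in the others. Tsix, which overlaps Xist on the other strand, was 102 in WT library 2 and 0 to 1.13 in the others.

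Across the cytotoxic, inhibitory receptor and TCR lists, 9 genes passed the threshold and were higher in KO, with a median log2 fold change of 1.61. With the mean of the CD8 T cell markers as a covariate 7 of the 9 stayed past limma's threshold, with a median of 1.77 over the 9. These genes had been chosen for passing in the same libraries. The marker mean itself did not clearly part the groups (KO minus WT difference 0.75, exact two-sided permutation p = 0.486). As a covariate it could therefore remove little, so this does not decide on a larger share of T cell RNA as their cause. A marker mean measured with error may also remove too little. Ikzf2 (1.15, SE 0.23, then 1.10, SE 0.23) and Tnfrsf9 (2.26, SE 0.43, then 2.14, SE 0.45) ended at an adjusted p of 0.0557 each, with nearly the same fold. These genes were not followed under the macrophage covariate, with which 9 of all 38 genes kept their call. Whether other cells of the sort added to their rise was therefore not tested. All 3 lists also stayed past camera's threshold at the preset correlation with the covariate (medians 0.89, 0.76 and 0.44, adjusted p at most 1.22e-05). The CD8 marker list did not (0.19, adjusted p = 0.166), but the covariate is the mean of its own genes, so that outcome was fixed in advance. Without the covariate none of the 3 calls held in camera with an estimated correlation (adjusted p = 0.187, 0.187 and 0.148), which was not run with it. The lists as wholes therefore do not decide against a larger share. This list test was adopted with its result known, after an earlier one, the rise of the lists over that of the markers (0.289 over 64 tested genes, exact permutation p = 0.657), had decided nothing. A batch that parts libraries 1 and 2 from 3 and 4 is balanced over the groups, so a term for it leaves the fold changes as they are and decides nothing (35 of the 38 genes were among the 46 called with it), and the genotype of the host stays open as a hypothesis.

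The 4 MHC class II genes H2-Aa, H2-Ab1, H2-Eb1 and Cd74 had a median log2 fold change of 1.66. The mean of the CD8 T cell markers was again used as a covariate, which by construction brings down the median of those markers (from 0.74 to 0.19). With it all 4 were past limma's threshold (adjusted p at most 0.00437) with a median of 1.91. The 4 genes had been noticed as higher and stand in the dendritic cell list, not among the T cell markers. The marker mean did not clearly part the groups either (exact two-sided permutation p = 0.486). The covariate could thus hardly remove their rise, so this test does not decide on a larger T cell share. This test was adopted with its result known, after 2 others: no overlap between the groups, which 3 of the 4 met (H2-Ab1 was at 20401 in KO library 3 and 27074 in WT library 2), and the 4-gene mean (exact permutation p = 0.0286), which decides nothing for genes noticed as higher. More macrophage RNA is argued against by the macrophage markers, with a median of -0.458 and 17 of 19 negative, which leaves open a rise of class II within those cells. More dendritic or B cell RNA cannot be told apart from such a rise, since 2 of their 10 tested markers other than class II reached 1 fragment in every library (median -0.0689), and the host genotype also stays open.

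Macrophage transcripts were abundant in every library although the sort required CD3e and CD8. Of 19 macrophage and monocyte markers, 12 lay above the median CD8 T cell marker in all 8 libraries, with Lyz2 at 75242 to 211543. H2-Aa, which is in the dendritic cell list and not among these 19, was at 11605 to 79428. RNA of macrophages carried along with the sorted cells, as doublets, attached debris or free RNA, is a candidate source, and 1 of the 19 genes is also in another list, Apoe. How much of each library came from such cells was not measured, and no biological explanation was tested.

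Other splits of the 8 libraries into 4 and 4 were fitted in the same way, 35 in all. The real split gave the most genes past the threshold, 38 against at most 29 elsewhere (1 of 35), the most in one direction, 34 against at most 28 (1 of 35), and the most lists, 14 against at most 9 (1 of 35). With 35 splits, 1 of 35 is the smallest share possible, so chance is less likely for these but cannot be excluded. With an estimated correlation 0 of the 14 lists were called. For the 4 lower genes the splits do not speak against chance, since 3 of 35, the real one included, gave as many in one direction, with up to 28 elsewhere. The split with 29 genes was the one of libraries 1 and 2 against 3 and 4, and with that batch as a term the real comparison gave 46 genes, 42 higher and 4 lower.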

How the results depend on the processing

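Of the settings below, a pseudocount of 100, the batch term, the sets of libraries 1 and 2 or 3 and 4 alone, the omission of both libraries numbered 2 and the 2 marker covariates were chosen after seeing the data. The planned edgeR and DESeq2 tests were not run, because whole reads could not be recovered. The cause of the differences below was not tested, except where fewer libraries or tested genes enter by construction. Depth limits scarce genes: of genes expected at 2 to 4 fragments a median of 7.1% per library were undetected. A Poisson draw of fragments gives 6.45% and a draw of reads 1.2e-24%, so amplification of few fragments is a likely source of isolated zeros. At 4 to 8 fragments the observed median was 1.2% against 0.5% in the fragment draw, so the draw accounts for only part of the zeros there. This test was chosen after the fragment number had been fitted to the overall share undetected, so it tests the spread over levels alone. The simulation recovered 98% of abundant genes changed by 2 on the log2 scale, but it drew no fragments and so does not test this limit.

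All 38 genes kept their direction in every setting. Where libraries were left out this was fixed in advance, since their KO and WT values do not overlap. Of the 38, 6 (Cd74, Cxcl9, Dusp10, Gbp2, Iigp1 and Serpinb9) passed in each of the 17 planned settings other than the block. The scalings moved the median of all genes by less than 0.1. Against 38 genes, 34 higher and 4 lower, there were 63 (59 and 4) with a pseudocount of 10, 15 (15 and 0) with a minimum mean of 50 and 112 (94 and 18) with sample weights, and 7 were lower with quantile normalization. The added settings gave 85 (76 and 9) with a pseudocount of 100, 0 (0 and 0) with libraries 1 and 2 alone and 0 (0 and 0) with 3 and 4 alone, 21 (21 and 0) without both libraries numbered 2, 9 (9 and 0) with the macrophage covariate, and 2 lower of 42 with the CD8 covariate. In the limma fits of these 2 sets, 746 of 15383 and 815 of 16105 tested genes had an unadjusted p under 0.05, near the share that chance alone gives. Leaving out each library in turn gave 7 (without KO library 4) to 70 (without WT library 4) genes, 7 to 61 higher and 0 to 9 lower. The 14 lists became 7 (without WT library 2) to 12, 0 with an estimated correlation, 4 with libraries 1 and 2 alone, 9 without both libraries numbered 2 and 8 with the CD8 covariate. That covariate ended the camera calls of the naive and memory (adjusted p = 0.398, median -0.03), chemokine (0.0733), CD8 (0.166), B cell (0.166), macrophage (0.0938) and fibroblast (0.398) lists.

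The Mtdh log2 fold change ranged from -1.38 to -1.04 when each library was left out, with limma adjusted p of 0.0247 (without WT library 3) to 0.241 (without WT library 1). It lost its call also at -1.23 with a minimum mean of 50 (adjusted p = 0.0945), at -1.16 and -1.30 (0.751 and 0.863) in the 2 sets, at -1.15 (0.163) without both libraries numbered 2 and at -1.19 (0.449) with the macrophage covariate.

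With the replicate number as a block, 0 genes passed limma (0 higher, 0 lower, and 1101 with an unadjusted p under 0.05), Mtdh stayed at -1.23 (adjusted p = 0.0627) and 12 lists were called. The numbers do not pair single libraries: deviations from the group means correlated across genes at 0.016, 0.052, 0.076 and 0.037 for equal numbers, and KO library 2 alone correlated best with its own number. They do carry the split of libraries 1 and 2 from 3 and 4. All correlations within a set were positive, such as 0.072 for KO library 1 with WT library 2, and all across the sets were negative. The block therefore takes up that split too.

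The 104 named genes gave 1865 comparisons in planned settings, of which 1714 kept direction and side of the threshold, 80 ended a call, 34 gained one and 37 changed sign, none of a called gene. For called genes the omissions could not change the sign, since their groups do not overlap. With sample weights Top2a went to -0.00265, Cxcr4 to 0.139, Ucp2 to 0.021, Abca1 to 0.043, Hspa8 to 0.0164 and Ighm to -0.251. With quantile normalization Atp5b went to -0.0282 and Pf4 to 0.510, and with upper-quartile scaling Atp5b to -0.00489. The omissions of 1 library gave ranges across 0 for Zeb2 (-0.500 to 0.0710), Top2a (-0.171 to 0.275), Cxcr4 (-0.233 to 0.214), Ucp2 (-0.206 to 0.0597), Soat1 (-0.0534 to 0.388), Hmgcs1 (-0.108 to 0.404), Abca1 (-0.165 to 0.180), Atp5b (-0.177 to 0.140), Cacybp (-2.75 to 0.0398), Capg (-0.0823 to 0.270), Ighm (-0.311 to 0.380), Pecam1 (-0.588 to 0.261), Pf4 (-2.46 to 1.13), Plin4 (-2.65 to 0.279) and Fabp4 (-1.58 to 1.34). List medians moved by over 1.5 times in these planned settings: B and plasma cells (0.15) to 1.35 with quantile normalization, 0.67 with sample weights and 0.56 with no filter, CD4 and regulatory T cells (0.90) to 0.48 with a pseudocount of 10, 0.40 with no filter, 1.74 with quantile normalization and 1.85 with sample weights. Red blood cells and platelets (-2.93) moved to -1.37 with a pseudocount of 10 and -1.76 with quantile normalization, macrophages and monocytes (-0.46) to -0.25 and the naive and memory list (0.31) to 0.21 with sample weights. With a pseudocount of 100 the red blood cell median was -0.33, that of CD4 cells 0.12, of B cells 0.28, of dendritic cells 0.76 and of the cytotoxic list 0.75. With a minimum mean of 50 the CD4 and red blood cell lists had too few tested genes for a test, and the chemokine call ended (camera adjusted p = 0.0505), as it did with quantile normalization (0.0545). The fibroblast call ended with no filter (0.0688) and with the replicate block (0.0705), which also ended the B cell call (0.0723). For the 14 lists, 211 of 261 planned and 71 of 95 added comparisons kept the call. Among these camera settings the cytotoxic, inhibitory receptor, TCR and dendritic lists lost it only with an estimated correlation. Fry called the TCR list (adjusted p = 0.0327) but not the cytotoxic (0.0978), inhibitory receptor (0.0978) or dendritic (0.101) list.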

Other observations

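The tests of the interferon gamma list and of the resident-type macrophage list below had their outcomes written down before they were run, on patterns found in the same data, and the rest of this part was chosen after the values were seen. Several genes past the threshold lay outside the fixed lists and are named for that reason. The costimulatory receptor gene Icos was higher in KO by a log2 fold change of 2.23 (SE 0.39), Cd274, which encodes the checkpoint ligand PD-L1, by 1.32 (SE 0.24), and Ptpn22, a phosphatase that restrains T cell receptor signalling, by 1.31 (SE 0.27). Dusp10, a phosphatase of stress-activated MAP kinases, was higher by 1.77 (SE 0.24) and passed limma's threshold whichever library was left out, as did Cd74, Cxcl9, Gbp2, Iigp1 and Serpinb9. Pde4d, a phosphodiesterase that breaks down cyclic AMP, was higher by 2.16 (SE 0.38), and the G protein-coupled receptor genes P2ry10 and Gpr132 by 1.32 (SE 0.27) and 1.18 (SE 0.24). Their calls depended on single libraries: Icos and Pde4d passed in 5 of the 8 omissions (limma adjusted p up to 0.0968 and 0.0679 in the others, each without WT library 1), Cd274 in 3 (up to 0.151), and Ptpn22, P2ry10 and Gpr132 in 1, the omission of WT library 4 (up to 0.202, 0.168 and 0.185 in the others). With a minimum mean of 50 none of these 6 passed, with limma adjusted p of 0.0538 for Cd274 to 0.111 for Ptpn22. Ptpn22, P2ry10 and Gpr132 also did not pass in several scalings, for example with TMM (0.0677, 0.0522 and 0.0529).

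Libraries 1 and 2 of both groups differed from libraries 3 and 4 in 29 genes past the same threshold in limma, 28 of them lower in libraries 1 and 2. Of the 29 genes, 24 were small nucleolar RNAs and 0 were also past the threshold between KO and WT. Snord55, for example, was at 1334 to 1785 in libraries 1 and 2 and at 5470 to 6994 in libraries 3 and 4. The split is balanced over the groups, and the labels name no batch.

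A wider interferon gamma response in the KO libraries was put as a hypothesis, because Cxcl9, Gbp2, Iigp1 and the MHC class II genes respond to that cytokine. It was tested on 38 other genes known to respond to it, whose values had not been looked at and none of which is in the fixed lists, and 36 were tested. They were tested in the same libraries in which the first genes had been noticed. Several, such as Gbp5 and Gbp7, are of the same family as Gbp2. Their rise is therefore not independent of the pattern that prompted the test. Their mean log2 value was higher in KO by 0.847 (exact two-sided permutation p = 0.0286, the smallest that 70 arrangements allow), with 32 of 36 genes positive, a median of 0.68 and each KO library above each WT library. Camera gave p = 1.26e-11 at the preset correlation and p = 0.0154 with an estimated one. No single gene passed over all genes tested and 4 passed when adjusted over the list alone, among them Gbp5 (1.36, SE 0.39) and Cxcl10 (2.47, SE 0.75). The type I interferon list was also higher by camera (adjusted p = 9.93e-05 at the preset correlation, 0.390 with an estimated one). A response to that type and a change in which cells were carried along therefore remain open. A stronger response to interferon gamma in the tumours of KO hosts may also underlie these genes, in T cells, in the other cells of the sort or in both. The gene for the cytokine itself, Ifng, was at 598 ± 428 in KO and 88.8 ± 31.0 in WT (SD, n = 4 each; limma adjusted p = 0.730), with 39.6 in KO library 2.

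Fewer transcripts of resident-type macrophages in the KO libraries was put as a second hypothesis, because Fcrls and F13a1 were lower. It was tested on 20 genes of such cells, 16 of them tested, relative to the general macrophage and monocyte markers. Selenop and Stab1 were left out because their values were known, and for 6 of the 20 (Ccl8, Mertk, Cd209b, Ednrb, Vsig4 and Slco2b1) it was not checked that they had never been printed. The list was lower than the general markers by a difference of -1.03 (exact two-sided permutation p = 0.171), which does not decide it, and camera gave p = 6.69e-05 at the preset correlation and p = 0.0619 with an estimated one. Of the 16 genes 15 were negative, with Cd163 at -3.76 (SE 1.15) and Maf at -0.87 (SE 0.26), none passed over all genes tested, and 5 were lower when adjusted over the list alone. KO library 2, with the fewest fragments, had the lowest list mean, 4.76 against 7.17 to 8.77 in the other libraries, so a loss of scarce transcripts there may add to the difference of -1.03.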
